A study of Mus musculus with 24 samples.

How the data were processed

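Exosomal RNA from the serum of male C57BL/6N mice at 40 weeks was extracted with a miRNeasy micro kit and profiled by the authors on the NanoString nCounter Mouse v1 miRNA panel. Per the labels, mice received normal chow and tap water, or a high-fat diet with drinking water holding 23.1 g/L fructose and 18.9 g/L glucose, and carbon tetrachloride or corn oil into the abdomen at 1 injection per week. The deposited values are in the unit signal, as scaled digital counts in 1 table of 626 features by 24 samples. How exosomes were isolated, the imaging and scaling software, the cartridge of each sample and the number of animals per sample are not given in the sources used here. From the values, the authors multiplied the digital counts of each sample by 1 factor (0.397 to 5.72), which gave nearly equal geometric means of the 100 highest miRNAs (542 to 610), and raised values under 1 to 1. Positive and negative control probes were left unscaled. Dividing by the factor gave whole counts for 14571 of 14571 values above 1 (100%, tolerance 0.05 counts); 117 values in 9 libraries were listed as 1, 2 of them among the miRNAs tested. Recovery of counts was tested on simulated libraries, where 100% of 3290 counts were equal.

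The table holds 566 mouse miRNA probes, 33 viral miRNA probes, 8 negative and 6 positive controls, 6 ligation controls, 3 spike-in probes and 4 messenger RNA probes. A miRNA was tested if its recovered count exceeded the mean plus 2 SD of the 8 negative controls in at least 6 of 24 samples, which kept 158 miRNAs, 55 of them above that limit in all samples. Of the kept probes 4 are shared by several miRNAs and counted once. Total counts of 42478 to 1496818 per library set the precision; counting error was smaller than the spread between samples, with a chi-square per degree of freedom of at least 14 in each group. miRNAs are named as the table gives them, and no coordinates are used, as the table states no genome build.

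The main test was limma (version 3.58.1, R 4.3.3), with lmFit and eBayes with a trend on log2(deposited value + 1), 4 group means over all 24 samples, two-sided, and Benjamini-Hochberg adjusted p under 0.05 over the 158 miRNAs within each comparison. Comparisons were WD+oil, ND+CCl4 and WD+CCl4 against ND+oil, WD+CCl4 against WD+oil, against ND+CCl4 and against the mean of the other 3 groups, the interaction, and the F-test of any difference. Fold changes are 2 to the power of the log2 difference; each SE is the moderated one of limma; a sample shows the direction if it lies on that side of the mean of the reference group. In each comparison the named miRNAs are the 12 largest rises and 12 largest falls past the threshold (for the interaction and F-test the 5 and 5 with the smallest p). With fewer than 5 past it, the 5 rises and 5 falls with the smallest p are drawn on as values. miR-122, miR-192, miR-21, miR-34a, miR-221, miR-223, miR-451, miR-16 and miR-23a are named where the text speaks of their lists; miR-34a was not kept. List members are named as examples by smallest p. miR-148a and miR-30a outside the called lists, and the calls of alternatives, were chosen after their values were seen.

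A total of 19 miRNA lists were fixed from general knowledge: hepatocyte-enriched, erythroid, platelet-abundant, myeloid, lymphoid, muscle, neuronal, pancreas and endocrine, liver fibrosis (reported higher), antifibrotic, liver cancer (reported higher, and reported lower), lipid and glucose metabolism, let-7, miR-17-92, miR-29 and miR-30, miR-200, Dlk1-Dio3 and Sfmbt2. Of these 17 were tested; the pancreas list had 0 members kept and the miR-200 family 2. Lists were tested by camera with an inter-gene correlation of 0.01, by camera with an estimated correlation, and by fry, with adjustment over the lists within a comparison. The lists share members, as miR-122 in the hepatocyte, antifibrotic and liver cancer lists. Group differences in the haemolysis index, log2 total count and detected miRNAs were tested by exact two-sided permutation of the 2 groups, adjusted over 6 pairs. These choices and the alternatives of scaling, filter, pseudocount (0.5 and 10), test, covariates and left-out libraries were fixed before the data were examined. edgeR 4.0.16 and DESeq2 1.42.0 on recovered counts, background subtraction, spike-in scaling, 2 other filters, the libraries that stand apart left out, and each set of replicates alone were added after.

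Same-numbered samples were checked for pairing by correlating residuals. All 6 exceeded 0.1 for ND+oil with WD+oil (0.32 to 0.75) and for ND+CCl4 with WD+CCl4 (0.28 to 0.84). In the other 4 pairs of groups 3 to 5 of 6 did (medians 0.23 to 0.40, lowest -0.17), so samples there are not shown to be unlinked. The best match was the sample of the same number in 4 of 6 for each of the first 2 pairs, and in 0 to 3 of 6 for the others. Same-numbered samples also share a set of replicates, and both libraries that stand apart hold number 1. The correlations therefore need not mean pairing. The replicate block is given beside the comparisons of the first 2 pairs and the interaction, and for every comparison in the part on processing. On simulated data for WD+CCl4 against ND+oil with 158 miRNAs of which 40 changed, limma recovered 36.5% of changes of log2 1, 84% of log2 2, 99% of log2 3 and 99.5% of log2 4, with 4.5% false calls; camera called 20 of 20 lists of 7 members shifted by log2 2 and 0 unshifted ones, and smaller shifts were not simulated. Each simulated miRNA varied independently, and no difference between replicates 1 to 3 and 4 to 6 was simulated. In the data the estimated correlation between members was 0.805 for the hepatocyte-enriched list and 0.519 for the let-7 family. How often such correlated lists are called falsely was therefore not measured. Viral, control and messenger RNA probes were left out of the comparisons. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for permutation tests and plots.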

Results

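RNA from serum exosomes, the small vesicles that cells release into blood, was measured in 24 mouse samples with the NanoString nCounter mouse miRNA panel, which counts barcoded probes without amplification. The samples came from male C57BL/6N mice at 40 weeks and form 4 groups of 6: normal chow with corn oil injections (ND+oil), western diet with corn oil (WD+oil), normal chow with carbon tetrachloride, a liver toxin (ND+CCl4), and western diet with carbon tetrachloride (WD+CCl4). The labels name these groups normal, NASH (fatty liver with inflammation), cirrhosis and HCC (liver cancer) in that order. The series title concerns serum exosomal miRNAs as a diagnostic model for liver cancer. The total miRNA count recovered per library ranged from 42478 to 1496818 (median 207120), and 69 to 213 of the 566 mouse miRNA probes lay above the negative control limit. The labels do not state that the samples come from separate animals, so the p-values measure the spread between these samples.

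Red cell and total RNA measures were compared first. The haemolysis index, log2 miR-451 of red cells minus log2 miR-23a, was 3.45 ± 0.32 in ND+oil, 2.96 ± 0.62 in WD+oil, 3.86 ± 1.51 in ND+CCl4 and 3.13 ± 1.09 in WD+CCl4 (SD, n = 6). None of its 6 pairwise differences passed an exact two-sided permutation test (adjusted p from 0.61 to 0.734). ND+CCl4 lay below ND+oil by 0.412 in replicates 1 to 3 and above it by 1.23 in replicates 4 to 6. The log2 total count was 18.33 ± 1.19 in WD+CCl4 and 16.61 ± 1.06 in ND+oil, a 3.30-fold difference (n = 6, exact permutation p = 0.026, adjusted p = 0.134 over 6 pairs). It was 5.84-fold in replicates 1 to 3, in large part through WD+CCl4 replicate 1 (totals 1328912, 139911 and 146375, beside 42478 to 59157 in ND+oil). In replicates 4 to 6 it was 1.86-fold (326439 to 444733 beside 178252 to 204535). The groups did not overlap within either set of replicates, which the permutation did not keep apart. ND+CCl4 lay 3.64-fold above ND+oil (exact permutation p = 0.0671, adjusted p = 0.134), and WD+oil 1.24-fold above it (p = 0.584, adjusted p = 0.701). The number of detected miRNAs was 162 ± 41.7 in WD+CCl4 and 108 ± 24.5 in ND+oil (SD, n = 6, exact permutation p = 0.026, adjusted p = 0.156). The difference was 61.7 in replicates 1 to 3 and 45.3 in replicates 4 to 6. In this number too WD+CCl4 and ND+oil did not overlap within either set, which the permutation again did not keep apart.

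Replicate 1 of ND+CCl4 and replicate 1 of WD+CCl4 stood apart from the other 22 libraries. They lay at 23.7 and 22.3 on the first principal component, which held 44.2% of the variance, and no other library exceeded 6.84. Both libraries also had the highest total counts (1496818 and 1328912). On the scaled values their hepatocyte-enriched miRNAs were higher (median log2 difference 4.11 from the other 5 libraries of each group). Their myeloid (-2.36), lymphoid (-2.30), let-7 (-1.92) and erythroid (-1.83) lists were lower on the same values. Replicates 1 to 3 also differed from replicates 4 to 6: the median total count was 69551 in the first set and 254312 in the second, with overlap in the carbon tetrachloride groups, and 57 of 158 miRNAs differed between the sets by limma within groups, 25 higher and 32 lower in the second. The labels give no batch for these sets. Both sets hold 3 samples of each group.

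**Figure D1:**
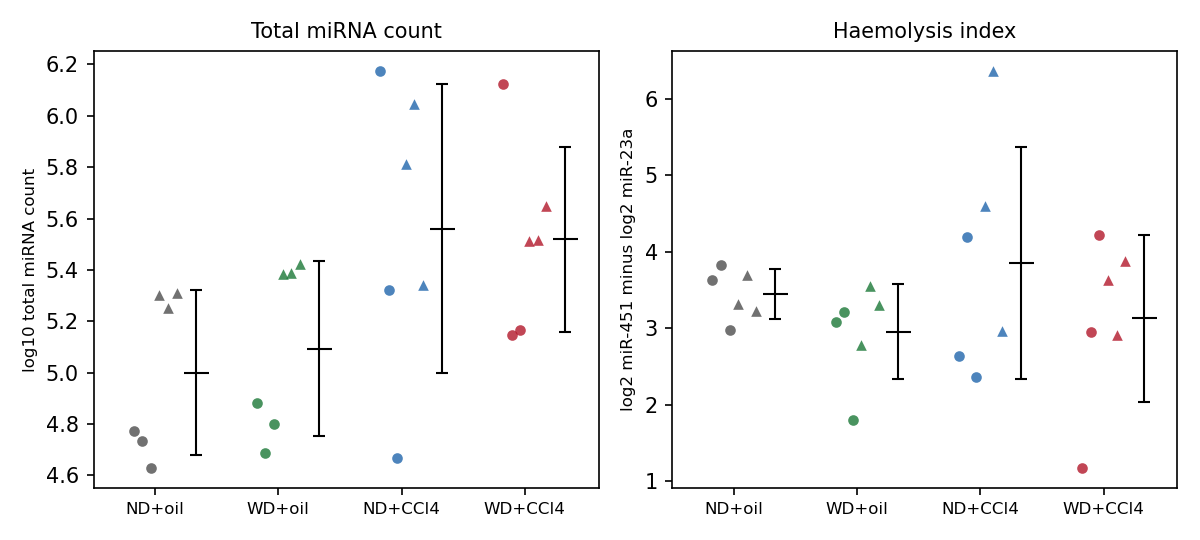
Log10 total miRNA count and haemolysis index (log2 miR-451 minus log2 miR-23a) of each library by group; circles are replicates 1 to 3, triangles replicates 4 to 6, and bars show mean ± SD of 6 libraries. Totals span 42478 to 1496818 counts and the index 1.17 to 6.37.

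The comparison of WD+oil with ND+oil shows what the western diet alone changed. miR-122, the most abundant miRNA of hepatocytes, rose 37.4-fold, from a log2 value of 7.27 ± 0.89 to 12.49 ± 0.80 (SD, n = 6), and miR-192, abundant in liver and gut, rose 8.96-fold (log2 3.16, SE 0.80). miR-1224 rose 3.87-fold (log2 1.95, SE 0.39), miR-540-3p of the imprinted Dlk1-Dio3 cluster 7.07-fold and miR-2137 4.33-fold. miR-342-3p and miR-146a, which are abundant in immune cells, rose 3.20-fold and 2.34-fold, and miR-132 rose 2.09-fold. In the other direction miR-669a of the Sfmbt2 intron cluster (log2 -1.46, SE 0.31), miR-125a-5p (-1.30, SE 0.31), let-7b (-1.29, SE 0.32) and miR-128 (-1.29, SE 0.38) fell. Each of these 12 miRNAs showed its direction in 6 of 6 samples, with limma adjusted p from 0.00036 (miR-122) to 0.036 (miR-2137 and miR-146a). In all, 17 of 158 miRNAs passed the threshold, 8 higher and 9 lower, among 46 at an unadjusted p under 0.05. The 5 further falls, miR-151-5p, miR-340-5p, miR-872, miR-20a with miR-20b on 1 probe, and miR-301a, lay between log2 -1.25 and -0.96. In 25 miRNAs the groups did not overlap, where chance gives 0.216% of miRNAs.

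Within replicates 1 to 3 and within replicates 4 to 6 miR-122 was 35.9-fold and 39.0-fold higher, miR-1224 4.94-fold and 3.03-fold, and miR-192 higher by log2 3.58 and 2.75. In the same order let-7b was at 0.375 and 0.447 of its control level. miR-192 lay under the negative control limit in ND+oil replicates 1 to 3 (108.7 to 168.8 beside limits of 169 to 198.9 in deposited units). Its fold in that set is therefore a ratio to background. The 5 hepatocyte-enriched miRNAs measured were all higher in WD+oil (median log2 2.002, camera adjusted p = 0.000265; adjusted p = 0.474 with an estimated correlation). miR-122 and miR-192 passed among all miRNAs and all 5 passed adjusted over the list alone, among them miR-148a at 2.002 (SE 0.67). The 9 let-7 family members were all lower (median -0.87, camera adjusted p = 0.0218; adjusted p = 0.666 with an estimated correlation); let-7b alone fell among all miRNAs, and 4 passed adjusted over the list alone. That list lost its call without ND+oil replicate 5 or replicate 6 (highest adjusted p = 0.0656). With the replicate number as a block, since same-numbered ND+oil and WD+oil samples were correlated, 37 miRNAs passed, and without the libraries that stand apart 52 passed. Leaving out libraries of the carbon tetrachloride groups does not change these log2 differences. It changes only the estimate of the spread, which all groups share. edgeR on recovered counts called 10, 8 higher and 2 lower, and DESeq2 30; centring on the median left 8 higher and 4 lower, no filter 4 higher and 1 lower, and scaling by spike-in probes 1, miR-122. The count was 34 without ND+CCl4 replicate 1, 31 without WD+CCl4 replicate 1, 6 without WD+oil replicate 3, 10 without ND+oil replicate 3 or 4, and 8 without ND+oil replicate 6. miR-192 and miR-340-5p lost their calls without WD+oil replicate 3 (adjusted p = 0.0523 and 0.0677), and miR-342-3p without WD+oil replicate 3, ND+oil replicate 4 or ND+oil replicate 6. Of the 24 fits that left out 1 library, miR-301a passed in 7, miR-2137, miR-146a and miR-872 in 16, miR-132 in 17, the miR-20a with miR-20b probe in 18, miR-128 in 19 and miR-151-5p in 22.

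**Figure D2:**
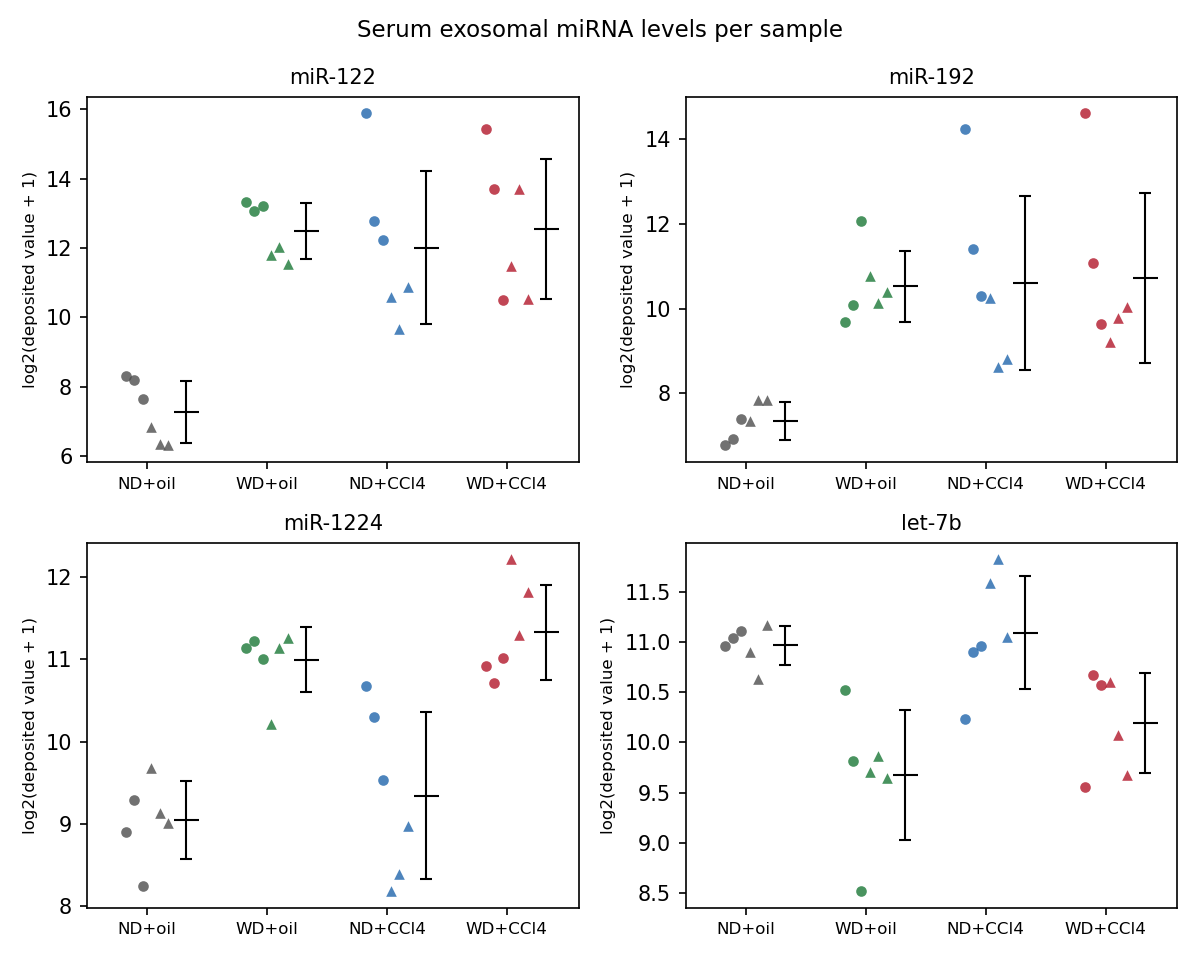
Log2(deposited value + 1) of miR-122, miR-192, miR-1224 and let-7b in each sample by group; circles are replicates 1 to 3, triangles replicates 4 to 6, and bars show mean ± SD of 6 samples. miR-122 lies at 7.27 ± 0.89 in ND+oil and at 12.49 ± 0.80, 12.01 ± 2.21 and 12.56 ± 2.02 in WD+oil, ND+CCl4 and WD+CCl4.

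The comparison of ND+CCl4 with ND+oil shows what carbon tetrachloride alone changed. miR-122 rose 26.7-fold, to a log2 value of 12.01 ± 2.21 (SD, n = 6; log2 fold change 4.74, SE 0.86), and miR-192 rose 9.46-fold (log2 3.24, SE 0.80). Both were higher in 6 of 6 samples and did not overlap the control group, with limma adjusted p of 0.0015 and 0.0368. No other miRNA passed, among 35 at an unadjusted p under 0.05; 4 miRNAs did not overlap between the groups, where chance gives 0.216%. The values nearest the threshold were log2 2.65 (SE 0.78, adjusted p = 0.125, 6 of 6 samples) for miR-376b of the Dlk1-Dio3 cluster, 1.14 (SE 0.39, adjusted p = 0.151) for miR-30c, -1.36 (SE 0.42, adjusted p = 0.125) for miR-762 and -1.62 (SE 0.54, adjusted p = 0.151) for miR-144, which red cells make together with miR-451. miR-122 was 48.4-fold higher in replicates 1 to 3 and 14.8-fold in replicates 4 to 6, and miR-192 30.6-fold and 2.92-fold. The 30.6-fold value is a ratio to background, as miR-192 lay under the negative control limit in ND+oil replicates 1 to 3. miR-122 lay just under it in ND+oil replicate 3 (196.9 beside 198.9 in deposited units). Both calls held with background subtracted. Without ND+CCl4 replicate 1 miR-122 was 15.6-fold higher and miR-192 5.72-fold.

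The hepatocyte-enriched list was higher in ND+CCl4 (5 of 5 members, median log2 1.64, camera adjusted p = 0.000172; adjusted p = 0.279 with an estimated correlation), with 2 members past the threshold and 3 adjusted over the list alone. Without the libraries that stand apart its median was 0.91. The Dlk1-Dio3 cluster was also higher (7 of 8 members, median 0.96, camera adjusted p = 0.00589; adjusted p = 0.279 with an estimated correlation), with no member past the threshold, 2 adjusted over the list alone, and a median of -0.42 when all probes were tested without a filter. Its adjusted p was 0.0688 without both libraries that stand apart, in which the cluster had a median log2 difference of 2.69 from the rest of their groups. edgeR called 12 and DESeq2 19 miRNAs, all higher, and a term for the sets 6, 4 higher and 2 lower. The count fell to 1 without any of ND+oil replicates 1 to 6 or ND+CCl4 replicates 1, 2 or 4, and was 10 without ND+CCl4 replicate 3 and 5 without ND+CCl4 replicate 6; miR-192 lost its call in 9 of these 24 fits (highest adjusted p = 0.119).

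The comparison of WD+CCl4 with ND+oil sets the group labelled HCC against the normal group. miR-122 rose 39.2-fold, to 12.56 ± 2.02 (SD, n = 6; log2 fold change 5.29, SE 0.86), miR-192 10.3-fold and miR-148a, another liver miRNA, 4.21-fold (log2 2.07, SE 0.67). miR-1224 rose 4.88-fold (log2 2.29, SE 0.39), miR-2137 4.87-fold, miR-432 4.16-fold, miR-540-3p 3.95-fold, miR-29c 3.01-fold and miR-2138 2.13-fold (log2 1.09, SE 0.37, adjusted p = 0.0442). Among the falls were miR-99a (log2 -1.998, SE 0.47), miR-29b (-1.82, SE 0.43), a repressor of collagen genes, and the blood cell miRNAs miR-181a (-1.78, SE 0.59), miR-144 (-1.64, SE 0.54) and miR-142-3p (-1.58, SE 0.50). let-7i (-1.75), miR-98 (-1.39) and let-7e (-1.33) of the let-7 family and miR-15b (-1.58) and miR-15a (-1.43) of a shared seed family also fell, with miR-151-5p (-1.49) and miR-125a-5p (-1.18). Each named miRNA showed its direction in 6 of 6 samples, with limma adjusted p from 0.000273 (miR-122 and miR-1224) to 0.0468 (miR-540-3p). In all 25 miRNAs passed, 9 higher and 16 lower, among 55 at an unadjusted p under 0.05, and 16 did not overlap between the groups, where chance gives 0.216%. The control libraries are those of the preceding comparisons, so the lists of changed miRNAs are not independent, and no overlap between them was counted.

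The hepatocyte-enriched list was higher (5 of 5 members, 3 past the threshold, median log2 2.07, camera adjusted p = 0.00185; adjusted p = 0.501 with an estimated correlation), and its median was 1.51 without the libraries that stand apart. The let-7 family was lower (9 of 9 members, 3 past the threshold, 6 adjusted over the list alone, median -1.31, camera adjusted p = 0.0219; adjusted p = 0.568 with an estimated correlation). The let-7 median was 0.12 when scaled by spike-in probes, which moved the median of all miRNAs from -0.17 to 1.25. Its call was lost without WD+CCl4 replicate 1 or ND+oil replicates 5 or 6 (highest adjusted p = 0.0869). Within replicates 1 to 3 and 4 to 6 the folds were 36.2 and 42.5 for miR-122, 26.6 and 3.99 for miR-192, and 4.19 and 5.68 for miR-1224, while miR-99a was at 0.246 and 0.255 of the control level. The miR-192 fold in replicates 1 to 3 is again a ratio to control values under the negative control limit. The split of 9 higher and 16 lower depended on the scaling and background: edgeR called 31 higher and 8 lower, DESeq2 31 and 16, background subtraction 17 and 6, median centring 8 and 6, no filter 4 and 6, and spike-in scaling 9 and 0. Without the libraries that stand apart 43 passed, 18 higher and 25 lower, including all 25. The count was 43 without ND+CCl4 replicate 1, 15 without WD+oil replicate 1 or WD+CCl4 replicate 5, 14 without WD+CCl4 replicate 3, 11 without WD+CCl4 replicate 1 or 6 or ND+oil replicate 4, 10 without ND+oil replicate 1, 8 without ND+oil replicate 2 or 3, and 7 without ND+oil replicate 6. miR-122, miR-192, miR-1224, miR-99a, miR-29b, miR-151-5p and miR-15a passed in all 24 fits that left out 1 library. miR-540-3p passed in 8 of them, miR-2138 in 10, miR-181a, miR-142-3p and miR-15b in 13, miR-148a, miR-144 and let-7e in 14, miR-432, miR-29c and let-7i in 15, miR-2137 in 19, miR-98 in 20 and miR-125a-5p in 22. Without WD+CCl4 replicate 1 miR-192 was 6.01-fold higher.

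**Figure D3:**
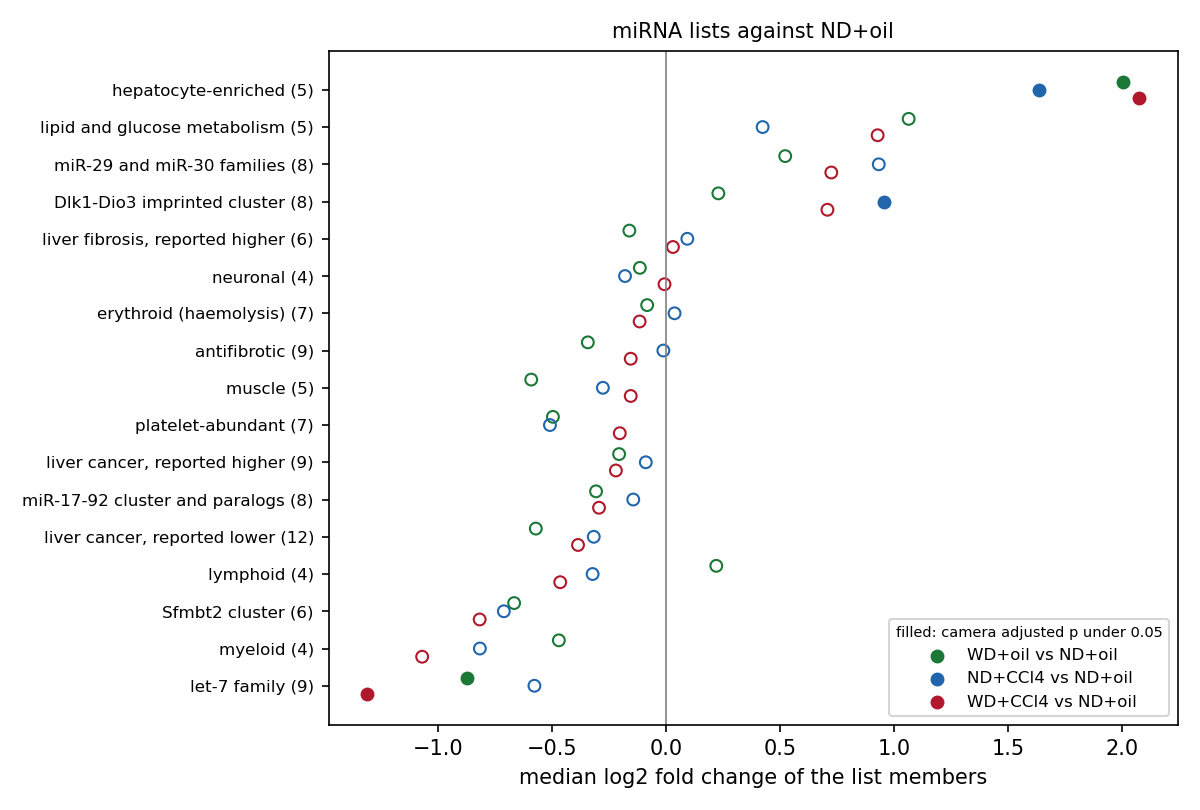
Median log2 fold change of the kept members of 17 miRNA lists (number of members in brackets) in WD+oil, ND+CCl4 and WD+CCl4 against ND+oil; filled points passed camera with the preset correlation. The hepatocyte-enriched list lies at 2.002, 1.64 and 2.07, and the let-7 family at -0.87, -0.58 and -1.31, the last turning to 0.12 when scaled by spike-in probes.

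The comparison of WD+CCl4 with WD+oil shows what carbon tetrachloride changed on the western diet. By limma 0 of 158 miRNAs passed, with 8 at an unadjusted p under 0.05, and edgeR and DESeq2 also called 0. miR-122 stood at 1.05-fold (log2 0.07, SE 0.86, adjusted p = 0.991, higher in 3 of 6 samples) and miR-192 at 1.15-fold (log2 0.20, SE 0.80, adjusted p = 0.984). The values with the smallest p were -1.32 (SE 0.47, adjusted p = 0.887, lower in 6 of 6 samples) for the lymphoid miR-342-3p and -1.09 (SE 0.47, adjusted p = 0.887, 6 of 6) for miR-99a, both without overlap between the groups, and 0.78 (SE 0.31, adjusted p = 0.887, 6 of 6) for miR-340-5p. The lymphoid list had 4 of 4 members lower without passing (median -0.58, camera adjusted p = 0.0772). Background subtraction with a term for the sets called 4 miRNAs.

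The comparison of WD+CCl4 with ND+CCl4 asks what the diet added to carbon tetrachloride, between the groups labelled HCC and cirrhosis. miR-1224 alone rose, 3.97-fold, from a log2 value of 9.34 ± 1.01 to 11.33 ± 0.58 (SD, n = 6; limma log2 1.99, SE 0.39, adjusted p = 0.00394, 6 of 6 samples). Other values that did not pass were 2.40 (SE 0.66, adjusted p = 0.0952, 6 of 6) for miR-432, 1.81 (SE 0.66, adjusted p = 0.218) for miR-2137, -1.06 (SE 0.31, adjusted p = 0.132) for miR-125a-5p and -0.90 (SE 0.32, adjusted p = 0.218) for let-7b. miR-122 stood at 0.55 (SE 0.86, adjusted p = 0.897). The miR-1224 fold was 1.64 in replicates 1 to 3 (adjusted p = 0.989) and 9.60 in replicates 4 to 6 (adjusted p = 7.58e-06), and its call was absent when scaled by spike-in probes (log2 2.03, adjusted p = 0.997) and, at an unchanged log2 of 1.99, with only the compared groups fitted (adjusted p = 0.112). The let-7 family was lower as a list (9 of 9 members, none past the threshold, median -0.80, camera adjusted p = 0.0115; adjusted p = 0.993 with an estimated correlation), but not without WD+CCl4 replicate 1 or ND+CCl4 replicates 4, 5 or 6 (highest adjusted p = 0.579, at a median of -0.48 without WD+CCl4 replicate 1). It was also lost in replicates 1 to 3 (median -0.35, adjusted p = 0.225) and with a haemolysis covariate (-0.50, adjusted p = 0.405). In 2 miRNAs, miR-1224 and miR-432, the groups did not overlap, where chance gives 0.216%, and 19 had an unadjusted p under 0.05. With the replicate number as a block, since same-numbered samples of these groups were correlated, 3 miRNAs passed, by edgeR 3 and by DESeq2 13. The count was 10 without ND+CCl4 replicate 1, 5 without WD+CCl4 replicate 2, 3 without WD+CCl4 replicate 1, 2 without ND+CCl4 replicate 2 or 3, and 8 without both libraries that stand apart.

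Against the mean of the other 3 groups, the contrast closest to a marker of the group labelled HCC, miR-1224 alone was higher in WD+CCl4, 2.90-fold (limma log2 1.54, SE 0.31, adjusted p = 0.00799, 6 of 6 samples). It was also 3.87-fold higher in WD+oil than in ND+oil. Between WD+CCl4 and WD+oil miR-1224 did not pass, and their log2 values overlapped (10.71 to 12.22 and 10.21 to 11.26). The call is thus not shown to set the group labelled HCC apart from the other group on the western diet. The next values were 1.71 (SE 0.54, adjusted p = 0.148) for miR-432, -1.34 (SE 0.39, adjusted p = 0.145) for miR-99a and -1.13 (SE 0.35, adjusted p = 0.148) for miR-29b, and miR-122 stood at 1.97 (SE 0.70, adjusted p = 0.208, 4 of 6 samples). The let-7 family was lower as a list (9 of 9 members, median -0.73, camera adjusted p = 0.0255; adjusted p = 0.653 with an estimated correlation), at 0.19 when scaled by spike-in probes; its call was lost without WD+CCl4 replicates 1 or 2, ND+CCl4 replicate 4 or ND+oil replicate 6 (highest adjusted p = 0.744, at a median of -0.41 without WD+CCl4 replicate 1), and without both libraries that stand apart (-0.56, adjusted p = 0.149). It held in 15 of 24 alternative fits. No miRNA of WD+CCl4 lay wholly outside the other 18 samples, where chance gives 0.00149%, and 23 had an unadjusted p under 0.05. miR-1224 was 1.80-fold higher in replicates 1 to 3 (adjusted p = 0.801) and 4.68-fold in replicates 4 to 6 (adjusted p = 0.000137). Its call was lost without WD+CCl4 replicate 4 (adjusted p = 0.0615), in the rank test and with spike-in scaling. The log2 difference of miR-1224 stayed between 1.36 and 1.66 when 1 library was left out, and between 0.847 and 2.48 over the other alternatives. edgeR and DESeq2 each called 8 miRNAs, the block 7, and 14 passed without ND+CCl4 replicate 1.

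The interaction of diet and carbon tetrachloride asks whether the effect of one depends on the other. By limma 0 miRNAs passed, with 6 at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2. With the replicate number as a block 1 passed. miR-122 had the largest value: its difference with carbon tetrachloride was smaller on the western diet (interaction -4.67, SE 1.21, adjusted p = 0.112), and miR-192 stood at -3.04 (SE 1.14, adjusted p = 0.459). miR-669a stood at 1.45 (SE 0.43, adjusted p = 0.193). As a list the hepatocyte-enriched miRNAs passed (5 of 5 members lower, median -1.57, camera adjusted p = 4.08e-06; adjusted p = 0.227 with an estimated correlation, 0.343 by fry). That median was -0.84 without ND+CCl4 replicate 1 and -2.13 without WD+CCl4 replicate 1. The miR-122 term passed with a term for the sets (adjusted p = 0.00766) and with background subtracted (adjusted p = 0.0368), and without the libraries that stand apart both miR-122 and miR-192 passed (-4.47 and -3.09, adjusted p = 0.00577). The count was 2 without WD+CCl4 replicate 1 and 1 without ND+CCl4 replicate 5.

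Across the 158 miRNAs, which are not independent replicates, the diet effect without and with carbon tetrachloride had Pearson r = 0.543 and Spearman rho = 0.579 (one-sided permutation p = 0.04 from 100 relabellings), with r = 0.136 in replicates 1 to 3 and 0.657 in replicates 4 to 6. The carbon tetrachloride effect on normal chow and on the western diet had r = 0.436 and rho = 0.485 (permutation p = 0.17). That r was 0.608 in replicates 1 to 3 and 0.036 in replicates 4 to 6, and 0.014 without the libraries that stand apart. The effects set against each other within a relation share no libraries, while both relations use the same 24 libraries.

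Any difference among the 4 groups was found for 17 of 158 miRNAs by the limma F-test, 8 higher and 9 lower in WD+CCl4 than in ND+oil, among 51 at an unadjusted p under 0.05. miR-1224 and miR-122 had the smallest adjusted p (0.000175 each), followed by miR-340-5p (0.00459), miR-125a-5p (0.00943), let-7b (0.0108), miR-192 (0.0152), miR-669a (0.0173), miR-151-5p (0.022), miR-342-3p and miR-132 (0.0338 each). edgeR called 26, DESeq2 55 and the rank test 0. The count was 32 without ND+CCl4 replicate 1, 26 without ND+CCl4 replicate 3, 11 without WD+oil replicate 1 or ND+oil replicate 4, 9 without WD+oil replicates 2 or 3 or ND+oil replicate 3, 7 without ND+oil replicate 6 and 5 without ND+oil replicate 1.

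Apart from the hepatocyte-enriched, let-7 and Dlk1-Dio3 lists no list passed camera in any of the 7 comparisons; medians are given for WD+CCl4 against ND+oil. Among blood cell lists, the erythroid list stood at -0.12 (0 of 7 members higher, adjusted p = 0.441; miR-144 and miR-15b fell), the platelet list at -0.20 (1 of 7 higher, adjusted p = 0.635; miR-191 at -1.12, SE 0.33, adjusted p = 0.0302, fell), the myeloid list at -1.07 (1 of 4 higher, adjusted p = 0.441; miR-142-3p fell) and the lymphoid list at -0.46 (2 of 4 higher, adjusted p = 0.769; miR-181a fell). miR-451, miR-16 and miR-23a themselves stood at -0.10 (SE 0.48), -0.12 (SE 0.29) and 0.22 (SE 0.23), and miR-223 at -1.02 (SE 0.51, adjusted p = 0.15). Among liver disease lists, miRNAs reported higher in fibrosis stood at 0.03 (3 of 6 higher, adjusted p = 0.69), with miR-21 at 0.59 (SE 0.54) and miR-221 at 0.15 (SE 0.35). The antifibrotic list stood at -0.15 with a mean of 0.62 (4 of 9 higher, adjusted p = 0.441), holding miR-122 and miR-29c, which rose, and miR-29b, which fell. miRNAs reported higher in liver cancer stood at -0.22 (3 of 9 higher, adjusted p = 0.441; miR-151-5p fell). Those reported lower stood at -0.39 (3 of 12 higher, adjusted p = 0.619; miR-99a, miR-29b and miR-125a-5p fell, miR-122 and miR-29c rose).

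The lipid and glucose metabolism list stood at 0.93 (4 of 5 higher, adjusted p = 0.125, with miR-27b at 1.21, SE 0.52), the miR-29 and miR-30 families at 0.73 (6 of 8 higher, adjusted p = 0.315, with miR-30a at 1.80, SE 0.69), and the Dlk1-Dio3 cluster at 0.71 (7 of 8 higher, adjusted p = 0.0954; miR-540-3p rose). The miR-17-92 cluster stood at -0.29 (1 of 8 higher, adjusted p = 0.441; the miR-20a with miR-20b probe fell), and the Sfmbt2 cluster at -0.82 (0 of 6 higher, adjusted p = 0.146, with miR-669a at -0.87, SE 0.31). The muscle list stood at -0.15 (2 of 5 higher, adjusted p = 0.826) and the neuronal list at -0.01 (2 of 4 higher, adjusted p = 0.826; miR-128 fell). Against ND+oil the median and mean of a list differed in sign for the antifibrotic list in all 3 treated groups (-0.34 and 0.59, -0.01 and 0.75, -0.15 and 0.62), and in ND+CCl4 for the erythroid list (0.04 and -0.40) and miRNAs reported lower in liver cancer (-0.32 and 0.17). Of the 119 list tests 9 passed camera with the preset correlation, 0 with an estimated correlation and 8 by fry. The fry calls against ND+oil were, upward, the hepatocyte-enriched list in WD+oil and WD+CCl4 (adjusted p = 0.0142 and 0.0209) and lipid and glucose metabolism in both (0.0288 and 0.0209). Downward they were the let-7 family in WD+CCl4 (0.0261), the Sfmbt2 cluster in both (0.0142 and 0.0178), and in WD+CCl4 the miRNAs reported higher in liver cancer (0.0209).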

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

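All tests of explanations in this part were chosen after the result was seen. In groups of 6 samples, the gap of the highest or lowest sample to its nearest neighbour was divided by the range, and 15 of 136 group and measure pairs exceeded the critical value of the Dixon test, where chance gives about 6.8; 9 of the 15 lie in replicate 1 of ND+CCl4 or of WD+CCl4. In ND+CCl4 replicate 1, miR-29c (0.878) and miR-148a (0.718) were high, and let-7e (0.746), miR-181a (0.706) and miR-99a (0.684) low. In WD+CCl4 replicate 1, miR-192 (0.656) was high, and miR-144 (0.678), miR-342-3p (0.65) and let-7i (0.633) were low. In WD+oil, miR-125a-5p in replicate 1 (0.809), miR-342-3p in replicate 3 (0.693), and miR-98 (0.688) and miR-301a (0.634) in replicate 2 were high, and miR-1224 in replicate 4 (0.76) was low. In ND+CCl4, miR-872 in replicate 2 was low (0.626).

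The effect of carbon tetrachloride on the hepatocyte-enriched list differed between the diets by the interaction (camera adjusted p = 4.08e-06, median -1.57; adjusted p = 0.227 with an estimated correlation). Without the libraries that stand apart the median was -1.41, with an adjusted p of 0.0293 with an estimated correlation. None of 111 tests of viral miRNA and messenger RNA probes against ND+oil passed (lowest adjusted p = 0.24, a lower value). As a set the 33 viral probes, which measure background here, lay lower by a median log2 of -0.74 in both ND+CCl4 and WD+CCl4 and -0.13 in WD+oil.

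On the scaled values, replicate 1 of ND+CCl4 and of WD+CCl4 lie higher in hepatocyte-enriched miRNA and lower in the blood cell lists than the rest of their groups. The Dlk1-Dio3 cluster (2.69) and the miR-29 and miR-30 families (1.89) were higher there too. Actb (36.1 and 36.5) and B2m (20.3 and 16.4) lay below all other libraries (lowest 140.8 and 162.3). Gapdh (90.6 and 106.9) lay above them (highest 54.5), and Rpl19 lay inside their range. What caused these differences was not tested. Both libraries had the highest total counts (1496818 and 1328912) and the lowest scale factors (0.397 and 0.457) of all libraries. A lower scaled level there need not be a lower amount. A different RNA yield with the same miRNA mix would move all miRNAs alike, which the pattern itself rules out: the log2 differences from the group had an SD of at least 2.05 across miRNAs, beside at most 1.30 in any other library. Red cell lysis alone, which would raise the share of red cell miRNA, is argued against as the cause. The share of miR-451 was 5.1% and 3.1% of their counts beside 9.7% to 65.6% in the other 22 libraries. As miR-451 belongs to the erythroid list, this share is part of the pattern and no separate test. A share also falls where other miRNAs raise the total, as in these libraries, so lysis beside another cause stays open. The haemolysis index alone does not decide it: the higher, 2.64, lay inside the range of the others (1.80 to 6.37), and miR-16 minus miR-23a was 0.199 and 1.18 beside a median of 0.74. Liver RNA added to an ordinary serum sample stays open: the median log2 difference of 4.11 in the hepatocyte-enriched list is the pattern itself and no separate test, while miR-451 (log2 count per spike-in 3.26 and 4.41) and miR-223 (0.06 and 0.59) lay inside the ranges of the other 22 libraries (-0.34 to 6.72 and -2.30 to 2.59). More severe liver injury in these samples and a difference in sample handling also stay open, as the labels hold no liver measurement and no handling record.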

How the results depend on the processing

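Alternatives added after the data were seen are the edgeR and DESeq2 fits, background subtraction, the filters on all 24 samples and on deposited values, spike-in scaling, the libraries left out together, and each set of replicates alone. Counts are given in the order WD+oil, ND+CCl4 and WD+CCl4 against ND+oil, WD+CCl4 against WD+oil, against ND+CCl4 and against the other 3 groups, the interaction, and the F-test, where the main test gave 17, 2, 25, 0, 1, 1, 0 and 17. Pseudocounts of 10 and 0.5, limma without the trend, robust limma, the 100 highest miRNAs as scaling, a filter on the mean level and the limit on deposited values kept every count within 1.5 times of these.

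With the replicate block the counts were 37, 19, 47, 0, 3, 7, 1 and 50, and with a term for the sets 33, 6, 41, 0, 3, 6, 1 and 37. Array weights gave 62, 2, 52, 0, 23, 15, 2 and 69, and the haemolysis covariate 16, 9, 26, 0, 3, 1, 1 and 23. Median centring gave 12, 2, 14, 0, 1, 1, 0 and 13, quantile normalization 23, 2, 28, 0, 1, 2, 1 and 23, and no filter 5, 2, 10, 0, 1, 1, 0 and 8, with more miRNAs to adjust over. The rank test gave 54, 0, 37, 0, 0, 0, no test of the interaction, and 0. Few miRNAs lay without overlap for ND+CCl4 against ND+oil and for WD+CCl4 against WD+oil and against ND+CCl4. Between 6 and 6 samples these alone could not pass the rank test. miRNAs with slight overlap can pass if enough do, as for WD+oil against ND+oil (54 calls, 25 without overlap), so the 0 calls were not fixed in advance. Fits of the compared groups alone gave 58, 2, 26, 0 and 0 in the first 5 comparisons and were not run for the rest. edgeR gave 10, 12, 39, 0, 3, 8, 0 and 26, edgeR with the set term 29, 12, 50, 0, 9, 7, 2 and 41, and DESeq2 30, 19, 47, 0, 13, 8, 2 and 55. Background subtraction gave 21, 2, 23, 0, 1, 1, 1 and 15, and with the set term 37, 9, 45, 4, 4, 7, 2 and 53. The filter on all 24 samples gave 13, 0, 9, 0, 1, 1, 0 and 8, with fewer miRNAs tested. Spike-in scaling gave 1, 3, 9, 0, 0, 0, 0 and 3. Without the libraries that stand apart the counts were 52, 2, 43, 0, 8, 5, 2 and 50, and with the set term as well 65, 8, 53, 0, 18, 19, 3 and 74. Replicates 1 to 3 gave 2, 1, 2, 0, 0, 0, 0 and 0, and replicates 4 to 6 gave 40, 1, 30, 0, 20, 20, 2 and 41, with 3 samples per group.

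Leaving out 1 library at a time gave 6 to 34, 1 to 10, 7 to 43, 0 to 0, 1 to 10, 0 to 14, 0 to 2 and 5 to 32 calls. The libraries behind these are named beside each result in the report. A left-out library outside the compared groups changes only the shared estimate of the spread, not the log2 differences. Lists past the threshold numbered 9, and 24 without a filter, 5 with a filter on the mean level, 15 with background subtracted, 2 with the filter on all 24 samples, and 7 to 13 when 1 library was left out. Lists were not tested under the rank test or DESeq2.

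Of the alternative values of the named miRNAs 943 stayed past the threshold in their direction, 153 lost the call and 4 changed sign, all with spike-in scaling in WD+CCl4 against ND+oil: miR-15a (0.006), miR-98 (0.029), let-7e (0.083) and miR-125a-5p (0.264). Of the values for the called lists 196 held, 19 lost the call and 3 changed sign: the let-7 median with spike-in scaling, 0.124 in WD+CCl4 against ND+oil and 0.19 against the other 3 groups, and the Dlk1-Dio3 median without a filter (-0.416) in ND+CCl4. Spike-in scaling put the median of all miRNAs at 1.25 in WD+CCl4 against ND+oil and at 0.88 against the other 3 groups. In WD+oil against ND+oil it was -0.03. The WD+CCl4 libraries held 13.91 to 305.3 miRNA counts per spike-in count, beside 6.96 to 36.72 in ND+oil. The spike-in reference itself varied, with a geometric mean of 2793 to 10836 counts per library. Its probe cel-miR-248 ran from 3847 to 32155, with medians of 13920.5 in replicates 1 to 3 and 4712 in replicates 4 to 6. Which scaling lies closer to the amounts in serum was not tested, nor was the cause of the Dlk1-Dio3 change. The relation of the carbon tetrachloride effects (r = 0.436) stood at 0.014 without the libraries that stand apart, -0.016 with the set term as well, and 0.036 in replicates 4 to 6. The relation of the diet effects (r = 0.543) stood at 0.136 in replicates 1 to 3. The haemolysis index difference of WD+CCl4 from ND+oil, -0.317, was 0.074 without the libraries that stand apart. Leaving out 1 library moved it between -0.534 and 0.074, that of ND+CCl4 from ND+oil between -0.094 and 0.706, and that of WD+CCl4 from WD+oil between -0.059 and 0.564; no index difference passed in any alternative. Where no cause is given, the cause was not tested. Libraries with few counts limit what can be seen: 69 miRNAs lay above the negative control limit in the smallest case and 213 in the largest.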

Other observations

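Every test in this part was chosen after the result was seen. Without replicate 1 of ND+CCl4 and of WD+CCl4, all 5 hepatocyte-enriched miRNAs passed as higher in WD+oil than in ND+oil, among them miR-148a (4.005-fold, limma adjusted p = 7.26e-05). miR-29c (2.29-fold, adjusted p = 0.000192) and miR-30a (3.37-fold, adjusted p = 0.00222) passed as higher as well. let-7i (-1.39, adjusted p = 0.0014) and miR-181a (-1.15, adjusted p = 0.00314) passed as lower. Neither left-out library belongs to WD+oil or ND+oil, so these differences are those of the main test. Only the estimate of the spread, which all groups share, changed. In that fit WD+CCl4 differed from ND+CCl4 also by a rise of miR-432 (6.90-fold, adjusted p = 0.019) and falls of miR-181a (log2 -1.68, adjusted p = 0.000978) and miR-99a (-1.13, adjusted p = 0.0139). In the main test miR-122 and miR-192 passed in WD+oil, and the other miRNAs named here did not pass in these comparisons, with an adjusted p of 0.0524 for miR-148a in WD+oil.

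Other splits of the samples were counted for each comparison. For WD+oil against ND+oil 1 of 100 splits, the real one, gave 17 calls and the highest other gave 1. Among the 32 splits that part all pairs of same-numbered samples the highest other was also 1. No share can fall below 1 of 100 or 1 of 32 here, and shares were not adjusted over the comparisons. Chance is thus unlikely for this count but not excluded. For WD+CCl4 against ND+oil 1 of 100 gave 25 and the highest other 2, and for the F-test 1 of 100 gave 17 and the highest other 3. The same limit holds for both. For ND+CCl4 against ND+oil 4 of 100 gave at least 2 and the highest other 7, and for WD+CCl4 against the other 3 groups 3 of 100 gave at least 1 and the highest other 32, shares under 0.05. For WD+CCl4 against ND+CCl4, 18 of 100 splits gave at least the 1 call seen and the highest other 40, so chance cannot be excluded; among the 32 splits that part all pairs 4 gave as many, and the highest other was 4. The splits with 7, 40 and 32 calls, several times the real counts, point to a structure of the samples. Known structures are the difference between replicates 1 to 3 and 4 to 6 (57 of 158 miRNAs) and the libraries that stand apart. Whether these splits follow either was not checked. With 0 calls, all 100 splits were as large for WD+CCl4 against WD+oil (highest other 3) and the interaction (highest other 0).

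In WD+CCl4 against ND+oil 16 miRNAs fell, by a median log2 of -1.46 (median SE 0.41). Background counts scaled up in the control libraries are argued against as the whole cause, since the median was -1.53 (median SE 0.59) after background subtraction, although only 6 of the 16 calls held there as the spread grew. The libraries that stand apart are argued against too: without them the median was -1.17 and all 16 passed. Scaling to equal geometric means in libraries with more miRNA may account for the falls, as spike-in scaling gave a median of -0.02 (median SE 0.82), while the median of all miRNAs moved from -0.17 to 1.25. These miRNAs were thus lower relative to the others, and whether their amount in serum fell stays open. Spike-in scaling does not settle it, as the spike-in counts also varied between libraries (cel-miR-248 from 3847 to 32155).

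miR-122 and miR-192 were higher than in ND+oil in all 3 treated groups, 6 log2 fold changes that share 1 control group. The libraries that stand apart are argued against as the cause, since the weakest of the 6 without them was 2.52 (SE 0.46) and all 6 passed. Spike-in scaling left the weakest at 3.26 (SE 1.13), with 5 of 6 past the threshold, and a haemolysis covariate left it at 2.67 (SE 0.64), with all 6 past it. In ND+oil replicates 1 to 3 miR-192 lay under the negative control limit, so the size of its rise is in part a ratio to background. A candidate explanation of the rises is release of hepatocyte RNA into blood in each of the injured liver states that the labels name. This is a hypothesis found on these data and was not itself tested, as the series holds no liver enzyme or histology values.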
